A study of Mus musculus with 2 samples.

How the data were processed

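RNA of B cells from AIRE transgenic and non-transgenic NOD mice was measured on 1 Affymetrix mouse array per group, with RNA from 2 mice in each. Per the labels, total RNA was isolated with a High Pure kit, and cDNA was fragmented and labelled with biotin before hybridisation. The deposited values are linear signal intensities, 1 per probe set and array, and were taken as the authors' processed values. The software, background step and scaling that the authors used were not given in the sources used here. In the deposited intensities the mean after leaving out the highest and lowest 2% of probe sets was 500.0 on both arrays, as a global scaling to a common target would give. The deposited intensities ranged from 0.1 to 58023 with a median of 93.1 on the transgenic array and from 0.2 to 98167 with a median of 104.3 on the non-transgenic array. The scale is therefore linear and uncentred, and a single-channel array has no dye direction. No detection calls were used here.

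The 64 control probe sets of the 45101 were set aside. Of the other 45037 probe sets, 34945 carry 1 gene symbol in the platform's probe table, 932 several and 9160 none, and only those with 1 symbol were named. Symbols were checked through Entrez identifiers against a table of RefSeq genes of assembly GRCm38.p6, used for names only, which held 34741 of these probe sets and renamed 0. No genome coordinates are given because the sources used here name no build.

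The rules for scaling, filtering, naming genes and gene lists were written before the data were examined. Because the log2 medians of the arrays differed by -0.16, which is beyond the limit of 0.1 set for this, each array was scaled so that its median met the pooled median (factors 1.06 and 0.947). Values under the pooled 25th percentile, 25.1, were then set to it and log2 was taken. A gene was represented by its probe set with the highest mean level and was kept if its higher value reached the pooled median, 98.8. At the floor were 11333 probe sets on the transgenic and 11193 on the non-transgenic array, and a ratio against the floor is a lower bound. With 1 array per group there is no test, p-value or standard error, and the number of arrays limits the precision.

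Named genes were Aire, the 12 genes with the highest and the 12 with the lowest ratio above the filter (placeholder symbols counted only), up to 4 members past 2-fold per list or otherwise the 2 of highest level, and the member of highest level of each cell type list. A gene named for another reason is said to have been chosen after its values were seen. The 477 genes at least 2-fold higher held 23 placeholders and the 344 lower ones 28. The 38 fixed lists cover AIRE and its cofactors, tissue antigens, antigen presentation, B cell subsets, cell states and other cell types. The ribosomal list leaves out kinases that share its prefix. For each list the median log2 ratio was placed among 10000 random lists of the same size, drawn from genes above the filter in 20 bins of mean level. The brightest bin held every gene above 5949, so the brightest genes were not closely matched. That percentile describes these 2 arrays. The shift of a list is its median minus the median of its random lists.

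The steps were tested on simulated arrays of 18194 genes with 200 given known folds in all their probe sets. These 200 were drawn only from brighter genes, with mean levels well above the filter, so the shares found do not hold for dimmer genes. Of 50 genes each, 44.0% were found at 2-fold when made 2-fold higher, 98.0% when made 4-fold higher and 100.0% when made 4-fold lower, and 6.21% of 10611 unaltered genes passed 2-fold by scatter. Of 200 unaltered lists of 20 genes, 6.0% lay outside the middle 95% of random lists. The scatter was drawn independently for each probe set, so genes of a list did not vary together as they may in real lists. Alternatives were quantile normalization, loess on the mean level, no scaling, other filters, floors, fold thresholds and probe set rules, and, added after seeing the data, leaving out probe sets whose names mark shared or cross-hybridising sequence. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.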

Results

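Gene expression was measured in B cells of NOD mice, an inbred strain that develops autoimmune diabetes, with and without a transgene for human AIRE. AIRE is the transcriptional regulator through which thymic epithelial cells express genes of other tissues, and the transgene was placed under an MHC class II promoter, a kind of promoter that is active in antigen-presenting cells such as B cells. The cells were negative for Thy1 and CD11c and positive for B220, which leaves out most T cells and dendritic cells, and they came from mice 8 weeks old. Each group was 1 array of RNA from 2 mice, so the only comparison was of 1 transgenic with 1 non-transgenic array. No difference given here has a replicate check, and every ratio describes these 2 arrays. The tissue from which the cells were taken was not given in the sources used here.

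The array carried 45037 probe sets besides its 64 control probe sets, and 10778 of 18194 named genes lay above the intensity filter. The median intensity as deposited was 93.1 on the transgenic and 104.3 on the non-transgenic array, and the medians were aligned before any ratio was taken. Intensities below are the aligned values, and ratios are log2 transgenic over non-transgenic, with values under the floor of 25.1 set to the floor. Levels correlated across genes above the filter with a Pearson r of 0.952, where genes are not independent replicates, and 92.4% of these genes lay within 2-fold. Their median log2 ratio was 0.19 with an SD of 0.58, against medians of 0.01 without the alignment, 0.05 after quantile normalization and 0.04 after loess. The 3′ to 5′ ratio of the beta-actin control probe sets was 1.49 on the transgenic and 1.25 on the non-transgenic array, that of Gapdh was 0.775 and 0.670, that of the transferrin receptor 4.20 and 4.59, and that of 18S ribosomal RNA 1.38 and 2.32. Hybridisation spikes, bacterial transcripts added as array controls, had a median log2 ratio of -0.70 over 18 probe sets. The probe sets of polyadenylated spikes had a median of 0.51, with 22 of 27 higher, and the 3 probe sets for 18S ribosomal RNA a median of 3.32. Each of these 3 medians kept its sign under all 4 scalings tried.

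**Figure D1:**
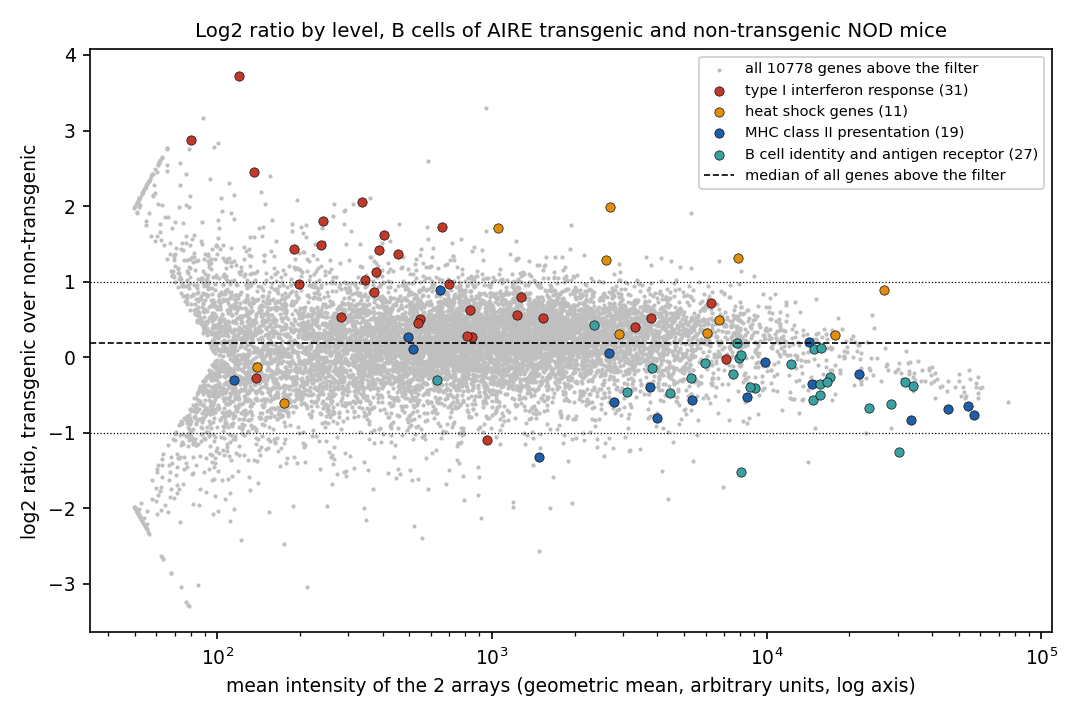
Log2 ratio of transgenic over non-transgenic intensity (vertical axis) against the mean log2 intensity of the 2 arrays (horizontal axis), with 1 point per gene above the filter. The spread was widest among dim genes, with an SD of 1.13 in the dimmest and 0.43 in the brightest of 10 bins of equal size. Genes with a mean under the filter were kept only if their higher value reached it, which by itself widens the spread in the dimmest bin.

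The comparison asked which transcripts of B cells differ when they carry the AIRE transgene. On the transgenic array, genes induced by type I interferon and natural killer cell markers were higher than genes of like intensity, and so were heat shock genes, except under 2 of 11 alternatives. The heat shock list was set beforehand as a marker of sample quality, and how the 2 samples were handled was not compared. Genes of MHC class II presentation, B cell identity, follicular and germinal centre B cells and the cell cycle were lower. Genes of other tissues that thymic AIRE is known to induce were mostly under the filter, and none of the 5 above it was at least 2-fold higher on the transgenic array. By size alone, 477 genes were at least 2-fold higher and 344 at least 2-fold lower on the transgenic array, a split of 58.1% higher. In 247 of the higher and 139 of the lower genes both values lay above the filter. On simulated arrays with the spread of these ratios, which includes any real difference, 659 of 10611 unaltered genes (6.21%) passed 2-fold, against these 477 and 344 of 10778. The split depended on the processing: it was 36.2% higher without the alignment (292 and 514 genes), 48.0% after quantile normalization, 49.0% after loess and 35.6% with the probe set of median ratio for each gene (242 and 438 genes).

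The endogenous Aire gene had 1 probe set, under the filter on both arrays, at intensities of 89.7 on the transgenic and 86.9 on the non-transgenic array (log2 ratio 0.05). It was designed on the mouse transcript and was not shown to read the human transgene, so it does not check the labels. Of 20 genes above the filter on the list of AIRE and its cofactors, 1 was 2-fold apart and the median log2 ratio was 0.36, within the middle 95% of level-matched random lists (0.02 to 0.42). That gene was Hnrnpl, an RNA-binding splicing factor, at 558 on the transgenic against 1131 on the non-transgenic array (-1.02), with its other probe set at -0.84.

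The highest ratio belonged to Mx2, an interferon-induced antiviral GTPase, at 437 on the transgenic against 33.1 on the non-transgenic array, 13.2-fold higher. H2bc21, a core histone H2B gene, followed at 2983 against 304 (9.82-fold), and its other probe set was also higher (1.76). Oas3, an oligoadenylate synthetase that senses double-stranded RNA, was 7.35-fold higher, Dkkl1, a protein of the sperm acrosome, 7.12-fold, and Agrn, the proteoglycan that organises the neuromuscular synapse, 6.88-fold. Cd1d2 was 6.75-fold higher (205 against 30.3), and as a near-identical copy of Cd1d1 it is uncertain which of the pair was read. Cd1d1 itself, chosen after its values were seen, was far brighter and differed less, at 10085 against 7262 (0.47), with its other probe set at 0.29. Another 6 of the 12 highest genes were at the floor on the non-transgenic array, so that their ratios are lower bounds. These were Cacna2d2, a calcium channel subunit, at least 6.83-fold, Noxo1, an organiser of NADPH oxidase, at least 6.82-fold, the tight junction gene Cldn12, at least 6.78-fold, the neuronal endosomal gene Nsg1, at least 6.29-fold, Bnip5, at least 6.23-fold, and Sytl1, a vesicle trafficking gene, at least 6.11-fold.

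At the other end, 3 genes at the floor on the transgenic array led. Pym1, a partner of the exon junction complex, was at least 9.82-fold lower, the testis actin-related gene Actl7b at least 9.75-fold, and the pancreatic elastase Cela3b at least 9.45-fold (24.9 against 237). Grip2, a scaffold of glutamate receptors, was 8.29-fold lower, Cep250, a protein that links centrioles, 8.22-fold (73.9 against 607), and Rab11fip4, a Rab effector, 8.11-fold with its other probe set at -2.12. Further genes at the floor on the transgenic array were Clmn, at least 7.29-fold lower, the triokinase Tkfc, at least 7.27-fold, the homeobox gene Msx3, at least 6.38-fold, Scrn1, at least 6.27-fold with its other probe set at -1.91, and the adaptor Grb7, at least 6.19-fold. Pou2f2, a transcription factor of the B cell lineage, completed the 12 lowest genes. It stood at 610 on the transgenic against 3618 on the non-transgenic array (-2.57), and its other 2 probe sets were both lower. Of the 12 highest and 12 lowest genes, only H2bc21 and Pou2f2 lay above the filter on both arrays. Without detection calls, the folds of the others and their order are uncertain.

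Genes of the type I interferon response were higher as a group. Of 31 members above the filter, 13 were at least 2-fold higher, 1 was at least 2-fold lower and 28 lay above the array-wide median ratio. The list's median log2 ratio was 0.86, above all of 10000 random lists matched on intensity (middle 95%, -0.05 to 0.36). Beside Mx2 and Oas3, the largest differences were in Ifit1, which binds foreign RNA caps, at 319 against 58.3 (2.45), and in Oas2, another oligoadenylate synthetase, at 683 against 164 (2.06). The lower gene was Stat2, a signalling component of the interferon receptor, at 653 against 1401 (-1.10), chosen for mention after its values were seen. Natural killer cell markers were higher on the same array, with a median of 0.71 over 11 genes (percentile 99.9 of random lists). Klre1, a lectin-like receptor of these cells, was at 470 against 192 (1.29), and the cytotoxic protease Gzma was at 2771 against 1370 (1.02).

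**Figure D2:**
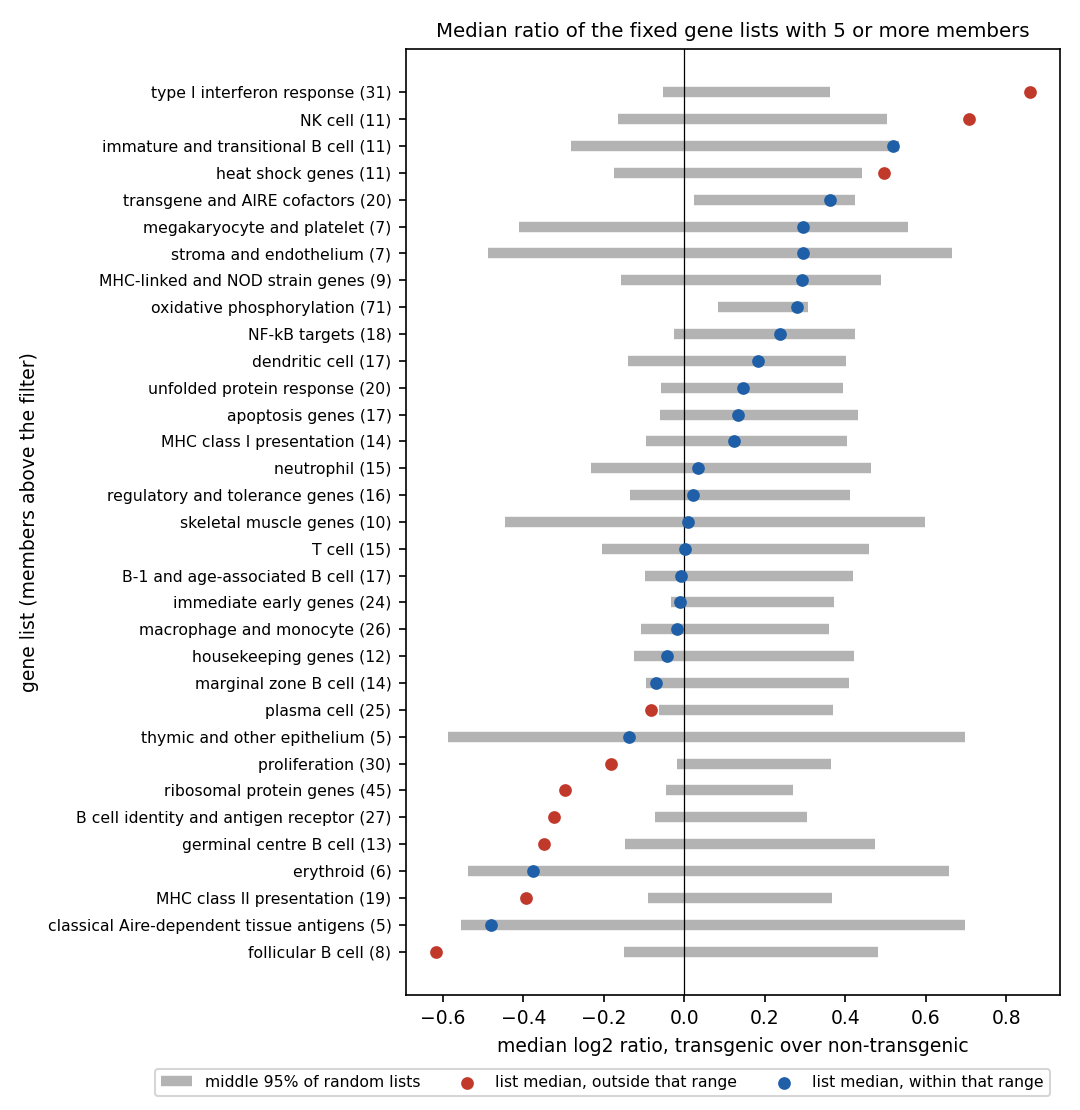
Median log2 ratio of each fixed gene list with at least 5 members above the filter (points, with the number of members in brackets) against the middle 95% of random lists of the same size matched on intensity (bars). The interferon list lay farthest above its bar at 0.86, and the follicular B cell list lay farthest below at -0.62.

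Genes of MHC class II presentation were lower as a group, with a median log2 ratio of -0.39 over 19 members (middle 95% of random lists, -0.09 to 0.37, percentile 0.0). Ciita, the master transactivator of MHC class II genes, was the only one of these at least 2-fold apart by its representing probe set, at 940 on the transgenic against 2359 on the non-transgenic array (-1.33), and its other 2 probe sets were both lower. Above the array-wide median ratio were 3 of the 19. Picked out after their values were seen, Cd86 was at 879 against 475 (0.89), and H2-Ea lay under the filter (86.5 against 61.5). The other probe set of H2-Ea was at 2.06. It was dim, with a mean level no higher than that of the first, and lay above the filter by its higher value only. Chosen after their values were seen, the class II beta chain H2-Ab1 was at 25083 against 44589 (-0.83) and the invariant chain Cd74 at 43668 against 74339 (-0.77). Very bright genes were also lower in general, with a median of -0.30 over the 20 genes at or above 30000 outside the class II, B cell identity and ribosomal lists. Genes of MHC class I presentation had a median of 0.12 over 14 members with none 2-fold apart (percentile 33.2). The class I light chain B2m was at 34653 against 39112 (-0.17) and the heavy chain H2-D1, whose paralogs share sequence with it, at 29646 against 31221 (-0.07), and both signs turned after quantile normalization (0.08 and 0.11).

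**Figure D3:**
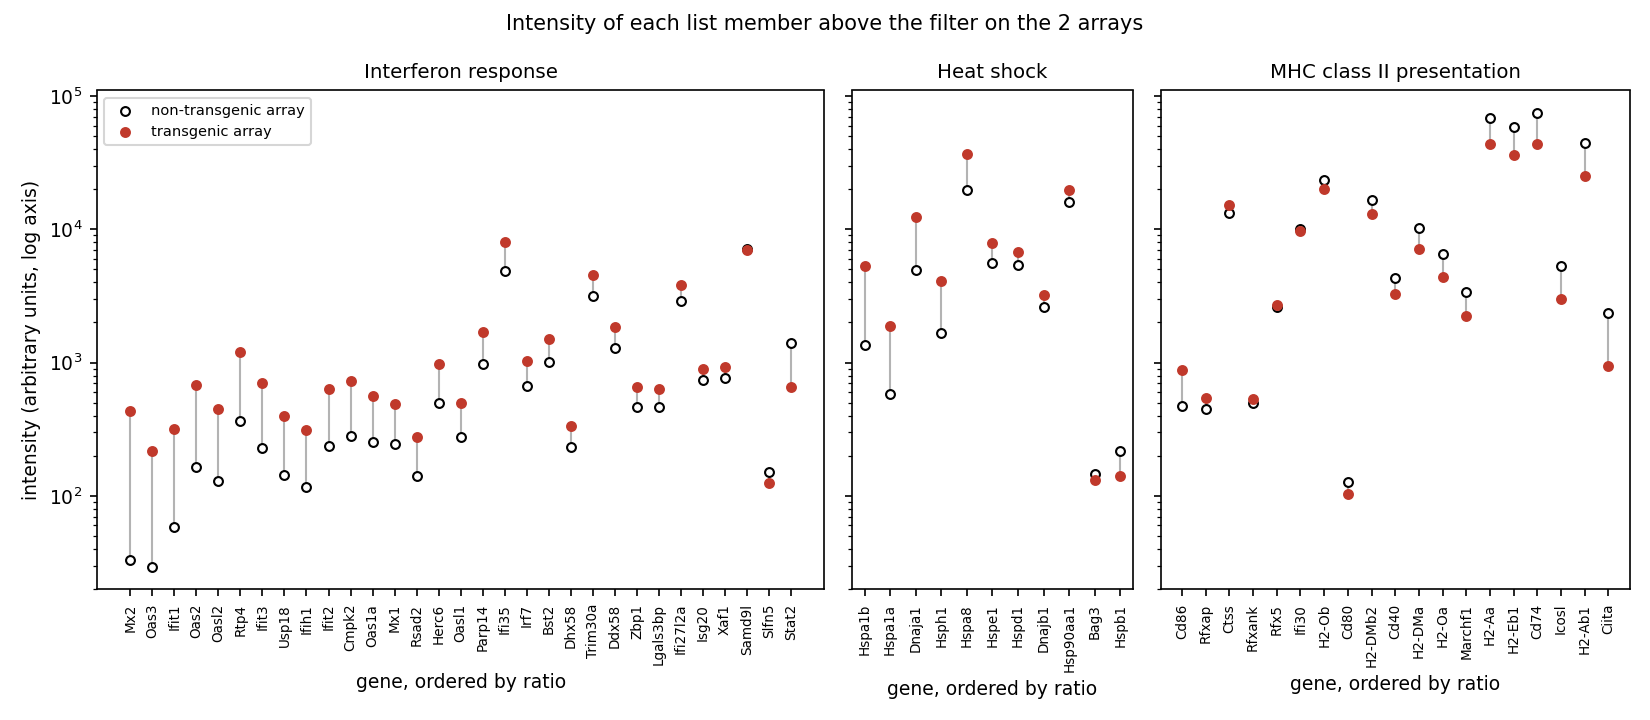
Intensity of every member above the filter (vertical log axis, arbitrary units) on the non-transgenic array (open points) and the transgenic array (filled points), for the interferon, heat shock and MHC class II lists, with genes ordered by ratio along the horizontal axis. Mx2 stood at 437 against 33.1 and Ciita at 940 against 2359.

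B cell identity genes were lower as a group, with a median of -0.33 over 27 members (middle 95%, -0.07 to 0.30), 2 of them at least 2-fold lower. These were Fcer2a, the low-affinity IgE receptor CD23 of mature B cells, at 4736 against 13654 (-1.53) with its other probe set at -2.16, and Cd79a, a signalling chain of the antigen receptor, at 19609 against 46825 (-1.26). The B cell surface gene Ms4a1 was at 29789 against 38866 (-0.38). The follicular B cell list, which shares Fcer2a, had a median of -0.62 over 8 members (percentile 0.0). In it the interleukin receptor chain Il4ra was at 967 against 2895 (-1.58), with other probe sets at -2.16 and 0.34, and Klf2, a transcription factor that controls B cell migration, at 8918 against 14446 (-0.70). Germinal centre genes had a median of -0.35 over 13 members (percentile 0.09) with 3 at least 2-fold lower. These were the transcription factor Mef2b at 52.6 against 237 (-2.17), Basp1 at 464 against 1231 (-1.41) and the sphingosine phosphate receptor S1pr2 at 212 against 554 (-1.39), whose other probe set was at 0.85. The list's gene of highest intensity, the transcriptional adaptor Lmo2, was at 2906 against 4682 (-0.69).

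Among genes of immature and transitional B cells, 4 of 11 were at least 2-fold higher, while the list's median of 0.52 lay within the middle 95% of random lists (-0.28 to 0.53, percentile 96.7). Its percentile was 97.9 after loess and 97.7 without the alignment, but 78.1 with both values above the filter and 73.7 with a filter at the 75th percentile. Vpreb1, a surrogate light chain of the precursor receptor, was at 178 against 30.0 (2.57), and Rag1, which cuts antigen receptor genes, was at 134.5 against a value at the floor, at least 5.36-fold higher. The progenitor transcription factor Myb was at 1920 against 780 (1.30) with its other 2 probe sets both higher, and Dntt, the terminal transferase of V(D)J joining, was at 146 against 61.8 (1.24) with its other probe set at 2.79. On the non-transgenic array Vpreb1, Rag1 and Dntt lay under the filter. Cd24a was at 22349 against 25227 (-0.17). Marginal zone genes had a median of -0.07 over 14 members (percentile 3.63, and under 2.5 with 3 of 11 alternatives), with Plac8 at 19467 against 24890 (-0.35) and Mzb1, a chaperone of IgM, at 19071 against 15474 (0.30). Genes of B-1 and age-associated B cells had a median of -0.01 over 17 members. Its only member 2-fold apart was Zbtb32, a zinc finger repressor, at 52.0 against 186 (-1.84), and its gene of highest intensity was the filament gene Vim at 6949 against 8149 (-0.23).

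Plasma cell genes had no member 2-fold apart among 25 and a median of -0.08 (percentile 1.5). Their position below the random lists was lost under 5 of 11 alternatives, such as the mean of a gene's probe sets (percentile 34.5). The immunoglobulin heavy chain gene Igha was at 21033 against 25370 (-0.27) and the joining chain Jchain at 18279 against 23590 (-0.37). Proliferation genes had a median of -0.18 over 30 members (percentile 0.07), 4 of them above the array-wide median ratio. The mitotic checkpoint kinase Bub1b was at 75.1 against 227 (-1.59), with other probe sets at -0.22 and 0.66, and the thymidine kinase Tk1 at 355 against 755 (-1.09).

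Heat shock genes had 4 of 11 members at least 2-fold higher and a median of 0.50 (percentile 99.0). The inducible chaperone genes Hspa1b, at 5334 against 1352 (1.98), and Hspa1a, at 1897 against 580 (1.71), are near-identical copies and were not told apart. Dnaja1, a co-chaperone, was at 12333 against 4981 (1.31), and Hsph1, a nucleotide exchange factor of these chaperones, at 4061 against 1671 (1.28), and the other probe sets of Hspa1b, Dnaja1 and Hsph1 were higher too. The list's place above the random lists was lost with the probe set of median ratio (percentile 93.3) and without probe sets marked as shared between transcripts (percentile 82.6), the latter an alternative added after seeing the data. Ribosomal protein genes had a median of -0.30 over 45 members (percentile 0.0), and after quantile normalization the list lay within the random lists (percentile 17.2). The random lists did not match its brightest members closely: 30 of the 45 lay at or above 30000, with a median of -0.31, where the 20 genes as bright outside the class II, B cell identity and ribosomal lists had -0.30. The 11 members under 10000 had a median of -0.29. Its only member 2-fold apart was Rps4l at 41.9 against 111 (-1.40). Oxidative phosphorylation genes had a median of 0.28 over 71 members (percentile 91.2, but 99.8 with the mean of probe sets and 99.5 with the probe set of median ratio), with the ATP synthase subunit Atp5k at 7318 against 3209 (1.19) and the complex I subunit Ndufc1 at 2679 against 1316 (1.03).

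The remaining cell state lists lay within the middle 95% of random lists. Immediate early genes had a median of -0.01 over 24 members (percentile 3.87, but 0.4 to 2.0 under 3 of 11 alternatives, quantile normalization among them), with the AP-1 component Jund at 8712 against 22881 (-1.39) and the nuclear receptor Nr4a3 at 179 against 74.2 (1.27). NF-kB targets had a median of 0.24 over 18 members, with the cytokine gene Tnf at 243 against 112 (1.12) and the chemokine gene Ccl3 at 803 against 401. Regulatory and tolerance genes had a median of 0.02 over 16 members with none 2-fold apart, and the inhibitory receptor gene Btla was at 10855 against 20841 (-0.94) and the inhibitory Fc receptor gene Fcgr2b at 9324 against 10115 (-0.12). Apoptosis genes had a median of 0.13 over 17 members, and the BH3-only gene Bad was at 567 against 148 (1.94) while its other probe set was at -0.14. Genes of the unfolded protein response had a median of 0.15 over 20 members, with the chaperone gene Dnajc3 at 2229 against 953 (1.23) and its 4 other probe sets also higher. Housekeeping genes had a median of -0.04 over 12 members (percentile 7.24, but under 2.5 with 2 of 11 alternatives), with the RNA polymerase subunit Polr2a at 3887 against 7976 (-1.04) and its other probe set at -2.26.

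Genes of other tissues were the group that bears on the known function of AIRE in the thymus. Of 21 classical Aire-dependent tissue antigens on the array, 5 lay above the filter, none was 2-fold higher and 2 were 2-fold lower, with a median of -0.48 (percentile 4.1). That median was 0.00 without the filter (percentile 50.1), and the list lay below the random lists under 3 of 11 alternatives, with percentiles from 0.5 to 1.9. The 0.00 is set by the floor, since members under it on both arrays, such as Fabp2 and Ttr, have that ratio by rule. It does not show that the whole list was unchanged. Pigr, the epithelial transporter of polymeric immunoglobulin, was at 92.9 against 218 (-1.23), and Pcp4, a calmodulin-binding peptide of Purkinje cells, at 524 against 1137 (-1.12). Of the islet antigens only 2 lay above the filter, with a median of -1.23 (percentile 2.46) that moved to 0.00 without the filter. This 0.00 too is set by members under the floor on both arrays, such as Iapp and Sst. Gad1, a glutamate decarboxylase and neuronal enzyme, was at 378 against 1217 (-1.69) with its other probe set at -1.38. Skeletal muscle genes had a median of 0.01 over 10 members, with the muscle glycogen phosphorylase Pygm at 56.7 against 121 (-1.09). Exocrine pancreas genes had a median of 0.25 over 4 members, with Cela3b lower as given above and the trypsinogen gene Prss2, one of a family of close copies, at 158 against 89.5 (0.82) with other probe sets at -2.15 and 2.79. Epithelial genes had a median of -0.14 over 5 members, with the thymic protease gene Prss16 at 152 against 215 (-0.50) and the cadherin gene Cdh1 at 214 against 152 (0.50).

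Markers of other blood cells lay within the middle 95% of random lists, the natural killer list excepted. T cell genes had a median of 0.00 over 15 members (percentile 22.4, but under 2.5 with 2 of 11 alternatives), with the coreceptor gene Cd4 at 155 against 38.4 (2.01), the sorting marker Thy1 at 101 against 208 (-1.04) and Cd2 at 2131 against 2845 (-0.42). Dendritic cell genes had a median of 0.18 over 17 members, with Batf3, a transcription factor of cross-presenting dendritic cells, at 69.8 against 179 (-1.36) and the lectin gene Clec10a at 713 against 310.4 (1.20). The chemokine receptor Ccr9 was at 1453 against 698 (1.06), with other probe sets at -0.31 and 0.26, and the protease inhibitor Cst3 at 8166 against 7922. Macrophage and monocyte genes had a median of -0.02 over 26 members, with the lipid carrier Apoe at 189 against 394 (-1.06) and the lysozyme gene Lyz1, a close copy of Lyz2, at 13492 against 7834 (0.78). Neutrophil genes had a median of 0.03 over 15 members, with the granule genes Ngp at 1011 against 371 (1.45) and Mpo at 106 against 50.7 (1.06), and the calcium-binding gene S100a8 at 3913 against 4393 (-0.17).

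The remaining marker lists had few members above the filter and lay within the middle 95% of random lists. Mast cell and basophil genes had a median of 0.60 over 2 members, with the stem cell factor receptor Kit at 135 against 63.8 (1.08) and the transcription factor Gata2 at 176.5 against 163. Erythroid genes had a median of -0.38 over 6 members (percentile 7.39, but under 2.5 with 2 of the 10 alternatives that gave a value), with the carbonic anhydrase gene Car2 at 439 against 549 (-0.32) and the haemoglobin gene Hba-a2 at 260 against 411 (-0.66). Platelet genes had a median of 0.30 over 7 members, with the integrin chain Itgb3 at 548.5 against 515 and the platelet chemokine Pf4 at 345 against 235.5 (0.55). Stroma and endothelium genes had a median of 0.29 over 7 members, with the adhesion gene Pecam1 at 1325 against 1443 (-0.12) and fibronectin, Fn1, at 787 against 594 (0.41). Adipocyte genes had a median of -0.03 over 3 members, with the desaturase Scd1 at 13730 against 17632 (-0.36) and the lipid carrier Fabp4 at 164 against 107 (0.62). The Y-linked genes Eif2s3y, at 2701 against 1836 (0.56), and Kdm5d, at 1680 against 1196 (0.49), were measured on both arrays, and the sex gene list had a median of 0.52 over 4 members (percentile 93.3, but 98.5 and 97.6 under 2 of 11 alternatives). Genes linked to the MHC or known to vary in NOD mice had a median of 0.29 over 9 members, of which the interferon-induced Mx1 was the only one 2-fold apart by its representing probe set, at 493 against 243 (1.02). H2-Ea, also on this list, was under the filter by that measure, with its other, dim probe set at 2.06 as given above.

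Of the 38 lists, 3 lay above and 8 below the middle 95% of random lists, where 1.9 would lie outside if all genes varied independently. Some lists share members, and genes of a list can vary together between 2 arrays. The excess over 1.9 is therefore not a measure of chance. Of the 27 lists within it, 9 lay outside under 1 or more alternatives. Probe sets of 1 gene differed by a pooled SD of 0.51 in log2 ratio, against an SD of 0.59 over the same probe sets, so that a 2-fold difference of a single probe set lay within 2 such SDs. Beside the disagreements given above, other probe sets lay on the other side for H2-D1 (2 of 6), Cd24a (1 of 2), Fcgr2b (1 of 3) and Kdm5d (1 of 1).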

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

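No tests are given in this part, and each value comes from probe sets that the gene comparisons did not use and was picked for its ratio. The 3 control probe sets for 18S ribosomal RNA had log2 ratios of 2.57 at the 3′ end (355 on the transgenic against 59.8 on the non-transgenic array), 3.32 at the 5′ end (258 against 25.8) and at least 3.42 in the middle (268 against a value under the floor). Of 3423 probe sets without a gene symbol above the filter, 206 were at least 2-fold higher and 147 at least 2-fold lower, with a median log2 ratio of 0.16. The 2 highest ratios among them were at least 2.80 (175 against 21.1) and at least 2.71 (165 against 18.2), both under the floor on the non-transgenic array. The 2 lowest were -3.14 (50.2 against 441) and -2.98 or lower (8.4, under the floor, against 198.5).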

How the results depend on the processing

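The alternative without probe sets marked as shared or cross-hybridising was the only one chosen after the results were seen. The count of genes at least 2-fold higher (477) was 292 without scaling, 941 without the filter, 170 with a filter at the 75th percentile, 247 with both values above the filter, 290 with the mean of probe sets, 242 with the probe set of median ratio, 286 with the floor at the median, 1879 at 1.5-fold, 132 at 3-fold and 1130 counted in probe sets. The count lower (344) was 918 without the filter, 94 at the 75th percentile, 139 with both values above the filter, 171 with the floor at the median, 907 at 1.5-fold, 116 at 3-fold and 970 in probe sets. Stricter filters and folds leave fewer genes by construction, and the cause of the other moves was not tested. Under all 11 alternatives, 7 lists kept their side of the random lists: interferon (shifts 0.32 to 0.73), natural killer (0.38 to 0.67), MHC class II (-0.67 to -0.39), B cell identity (-0.51 to -0.40), follicular (-0.83 to -0.74), germinal centre (-0.92 to -0.49) and proliferation (-0.44 to -0.23). Within these, interferon moved to 0.32 and germinal centre to -0.92 at the 75th percentile, MHC class II to -0.41 after quantile normalization and -0.39 with the probe set of median ratio, and proliferation to -0.23 with the mean of probe sets. Ribosomal genes (-0.44) moved to -0.05 after quantile normalization, -0.25 after loess, -0.36 at the 75th percentile, -0.32 with the mean and -0.34 with the median-ratio probe set, and were inside the random range under 1 of 11. Heat shock genes (0.33) were inside under 2, moving to 0.68 at the 75th percentile and 0.13 without shared probe sets. Plasma cell genes (-0.26) were inside under 5, moving to -0.07 with both values above the filter and -0.04 with the mean, and islet antigens (-1.34), with 2 members, under 6, moving to 0.00 without the filter. Without the filter, islet antigens under the floor on both arrays have a ratio of 0 by rule. No value was possible, for want of members, for the erythroid, exocrine pancreas, mast cell, platelet and epithelial lists at the 75th percentile and for mast cells with the probe set of median ratio. Of the values of single named genes, 1032 moved by less than 0.51, the SD between probe sets of 1 gene, and 66 moved further. Of 1099 values 21 lay on the other side of 0, where Bad, at -0.14 with the probe set of median ratio, was the only gene past 2-fold before. The others came from B2m, H2-D1, Cst3, Gata2, Itgb3 and Fn1, and from Xist, Nkg7, Pou2af1, Ly86 and Fcrla, which were chosen after their values were seen. Dim signal also limits single genes, since 43 of the higher and 42 of the lower genes had 1 value at the floor.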

Other observations

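The tests on plasmacytoid dendritic cells, on a smaller share of B cells and on compression of the brightest probe sets, and the comparison with genes of nearest intensity and the genes named for it, were chosen only after the results were seen. The bright genes of class II presentation were set against the 50 genes of nearest mean intensity outside the class II, B cell identity and ribosomal lists. The log2 ratios of H2-Aa (-0.65), H2-Eb1 (-0.69), Cd74 (-0.77) and H2-Ab1 (-0.83) each had 2 of those 50 genes below them, while H2-DMb2 (-0.36) had 8, H2-Ob (-0.23) had 10 and the protease Ctss (0.20) had 33. H2-Aa, H2-Eb1 and Cd74 were compared with the same 50 genes, whose mean intensities reached down to 20609 and whose median ratio was -0.17. Most of those were dimmer than these 3 genes, and the 20 such genes at or above 30000 had a lower median of -0.30. The antigen receptor chains Cd79a (-1.26) and Cd79b (-0.62) had 0 and 2 of 50 below them, the inhibitory receptor Cd22 (-0.68) had 2 and Ms4a1 (-0.38) had 9, while Fcrla (0.19) had 17 and Pou2af1 (0.11) and Ly86 (0.12) had 31 each.

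Scatter of single probe sets was weighed for the genes at least 2-fold apart, since probe sets of 1 gene often differ. Of 268 other probe sets of the 155 higher genes that have any above the filter, 70.1% lay above the array-wide median ratio (exact 95% interval 64.3 to 75.6), and 19.4% were at least 2-fold higher themselves. Of 90 other probe sets of 66 lower genes, 83.3% lay below it (74.0 to 90.4), and 33.3% were at least 2-fold lower. These shares argue against scatter as the whole cause of either count, and the intervals treat probe sets of 1 gene as independent. For genes with no other probe set above the filter it remains open, as does a difference by genotype, untested beyond 1 array each.

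Interferon genes were higher on the transgenic array, and 3 explanations were weighed. A trend of the ratio with brightness is argued against, since the list's shift after loess was 0.72 (median 0.76 against -0.17 to 0.24 for the middle 95% of random lists). The random lists were already matched on level, so loess added little to the shift of 0.69 found before it. Scatter of single probe sets is argued against for the 9 members with other probe sets, 13 in all with a median of 0.583 (random probe sets, -0.19 to 0.43). It stays open for the single large differences. Of the 13 genes at least 2-fold higher, only Cmpk2, named after its values were seen, had another probe set above the filter (0.32). More plasmacytoid dendritic cells, which make interferon and carry B220 but also some CD11c, against which the sort selected, cannot be told apart, because 7 of 9 markers above the filter had a median of 0.235 (random lists, -0.27 to 0.53) and went both ways, with Klk1 at 1447 against 593.5, Ccr9 at 1453 against 698 and Siglech at 830 against 882. An exposure of 1 pool of mice to interferon and a difference by genotype could both give this pattern and were not tested.

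MHC class II and B cell identity genes were lower on the transgenic array, with a joint shift of -0.494 over 46 genes. A trend with brightness is argued against by the shift after loess, -0.439 (median -0.40 against -0.12 to 0.16 for random lists), although those lists were already matched on level. Compression of the brightest probe sets is argued against only for the 26 members dimmer than 10000, with a shift of -0.474 (median -0.29 against -0.03 to 0.35). For the brighter members it stays open. Outside the class II, B cell identity and ribosomal lists, the 20 genes at or above 30000 had a median of -0.30, and the 195 at or above 10000 one of 0.04. A smaller share of B cells was tested as a like rise of the markers of other cell types. The sort selected against Thy1 and CD11c, so other types need not rise alike when that share falls. The T cell, natural killer, macrophage and neutrophil lists lay 0.676 apart, from -0.151 to 0.525, only just beyond the 0.661 that random lists gave. That argues narrowly against a like rise of all 4, but it cannot tell whether the share of B cells fell. It rests on the natural killer list, the only one of the 4 outside its random lists. More natural killer cells in place of B cells therefore stay open, although the B220-positive gate works against them. Of the natural killer list's 11 members, 8 lay above the array-wide median ratio. The others, Nkg7 (0.02), Prf1 (-0.06) and Xcl1 (0.00), stood near 0 and were chosen after their values were seen. A different mix of B cell subsets, GC content, for want of sequences, and an effect of the transgene itself were not tested and stay open.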
